A study of Danio rerio with 4 samples.

How the data were processed

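The series covers liver RNA of zebrafish larvae at 5 days post fertilisation (dpf). One group carries a transgene that drives human UHRF1 fused to GFP from the hepatocyte promoter of fabp10 and was labelled as the high line. UHRF1 is an epigenetic regulator that recruits the maintenance DNA methyltransferase to newly replicated DNA. The other group carries nuclear mCherry under the same promoter and is the control. The labels name 4 libraries, 2 per group. The table analysed here holds a value column for each of the 2 UHRF1-high libraries, A and B, and both were matched by name to their sample titles. The 2 control libraries were not analysed here. The planned test between the groups (a limma fit of log2 values with Benjamini-Hochberg adjustment, and set tests on the same fit) therefore could not be fitted, and no fold change against the control, no p-value and no count of changed genes is given. The analysis describes the levels in the UHRF1-high livers and how far the 2 libraries of that group differ. The number of other per-sample columns left unused was 0.

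Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected on beads and fragmented, and bar-coded adapters were added for sequencing. The series' design text speaks of small RNA, while the sample labels and the gene-level table describe messenger RNA. The deposited signal values are quantile-normalised by the authors, as the name of the deposited table states. Per the submitters' processing notes the genome build was Zv9 (danRer7) and CASAVA 1.7 was used. The counting method, the annotation, the unit before normalisation and the filter that chose the genes are not given in the sources used here, nor is the meaning of the ending "mult" in the column names. The table holds 11021 genes, each with a symbol and a genomic span. Of these symbols, 8848 are current in the RefSeq gene table of the GRCz12tu assembly, 1963 were matched through a unique older symbol and 210 were not matched. The matching was used for names only. The symbols are printed as the table gives them, and coordinates are those of the table, with the start counted from 1 (3 starts are 0 in the deposited table).

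Quantile normalisation gives every library nearly the same set of values, so a value reports a gene's rank in its library. The values sum to 860102 in A and 860084 in B, and these sums carry no information on sequencing depth, which is unknown. No counting intervals can be given. A gene at the top rank has the same value in both libraries whatever its true share of the RNA. After multiplication by 14, 99.8% of the distinct values were whole numbers of thousandths within a tolerance of 0.02, against 87.5% with 7 and 13.2% with 13. Averages over a set of libraries larger than the 2 analysed would have this property. Low values are heavily tied: 694 genes share the lowest value in A, 0.0203, and 449 genes are listed at 0 in B. At the second most common value of A, 0.183, there are 423 genes whose genomic spans have a 10th percentile of 3402 and a 90th percentile of 87668 bases. Whether values were divided by transcript length is not stated, so a difference in level or rank between different genes can include their length, while a comparison of 1 gene between A and B does not.

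Levels are given as the mean ± SD of the 2 libraries. Differences between libraries were computed on log2(value + 1), a scale that understates the difference of low genes, over the 8386 genes with a mean value of at least 1. The other 2635 genes entered only the correlations over all genes and the levels. There were 37 gene lists fixed before the data were examined, covering liver functions, the cell cycle, stress, immune and chromatin genes, and markers of other cell types; 8 lists for other tissues were added afterwards. The result of 1 of the 37 lists is not reported here, though the counts of lists include it. Members were matched through older symbols, and a list needed 5 members above the filter. For each list, the median difference between A and B was placed among the medians of 10000 random lists with the same number of genes from each of 20 level bins. A list outside the central 95% of random medians is said to stand apart. This percentile describes these 2 libraries and is no test, because genes of a list vary together and random lists do not. Intervals on differences between 2 list medians are 95% bootstrap intervals over genes from 10000 draws. They also treat genes as independent, are too narrow where genes vary together, and do not measure the spread between libraries. On data simulated for 8386 genes, 6 of 6 lists of 20 genes shifted by 0.5 or more (log2) stood apart in the right direction. Of 200 unshifted lists, 12 stood apart. The simulated differences were independent normal draws with 1 common SD, and the real levels set only the bins. The simulation therefore does not cover genes that vary together or smaller lists.

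The rule for named genes, fixed before the data were examined, put uhrf1 and dnmt1 first. The part that ranks genes by a test between the groups could not be applied. In its place the text names the genes of highest mean value, the 10 genes with the largest difference in each direction that have a name rather than a clone or locus placeholder, and up to 4 members of a list by mean level. These replacements, and further members named as examples, were chosen after the values were seen. The alternatives tried were pseudocounts of 0.1 and 10, no filter, a filter at a mean of 10, median scaling, a further quantile normalisation, leaving out the marker genes of other cell types, and using 1 library alone. Limma variants, set tests and fits without single libraries were planned and not run, since they need the control group. The groups have no replicate numbers in common, as 1 is lettered and the other numbered. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.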

Results

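Gene expression was measured by sequencing polyadenylated RNA from livers of 5 dpf zebrafish larvae. The study set livers that express human UHRF1 in hepatocytes at a high level against livers that express mCherry, with 2 libraries in each group. The values analysed here come from the 2 UHRF1-high libraries, A and B. They are quantile-normalised values for 11021 genes, with a median of 4.36 in A and 4.41 in B. All means below are over these 2 libraries (n = 2), and the SD is the spread between them. The labels do not say whether A and B came from separate clutches, and the series text speaks of batches without saying which library belongs to which. Sequencing depth is unknown. The question of which genes UHRF1 changed relative to mCherry livers was not analysed here, and no level below is a change against the control.

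The endogenous zebrafish uhrf1 gene, on chromosome 22 from 3857027 to 3887735 (Zv9), had a low value in both UHRF1-high libraries. It was 1.74 in A and 0.976 in B, a mean of 1.36 ± 0.541 (SD, n = 2). These values rank 7378th and 8291st among the genes. The human UHRF1-GFP transgene is not a zebrafish gene, so this value does not check the label. The gene for the maintenance DNA methyltransferase, dnmt1 (chromosome 3, 55442937 to 55458853), had values of 2.14 in A and 3.30 in B, a mean of 2.72 ± 0.823. The list of DNA methylation and associated silencing genes had 24 measured members with a median at percentile 34.6 of all genes in A and 36.1 in B. The highest of them were hdac1, a histone deacetylase, at 64.4 ± 6.34, mbd3a at 17.9 ± 1.17 and the thymine DNA glycosylase tdg at 11.0 ± 3.35. The de novo methyltransferase genes dnmt3aa (0.183 and 0.0609) and dnmt3ab (0.487 and 0.0609) lay near the lowest values. The list median differed between A and B by -0.12 on the log2 scale, and by 0.01 without a filter, within the range of random lists both times.

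Hepatocyte genes held the first 3 ranks of both libraries: the apolipoprotein genes apoa1b and apoa2 and the liver fatty acid binding protein gene fabp10a. The elongation factor gene eef1a1l1 was next in both. By mean value slc25a5, rps2, tfa, rplp0, rpl26 and pklr followed, of which rps2, rplp0 and rpl26 encode ribosomal proteins. The 10 highest values made up 35.0% of the summed value in each library, a share set by the normalisation. The list of secreted and other abundant hepatocyte proteins had 48 measured members, whose median lay at percentile 96.6 in A and 94.6 in B. Of the 47 above the filter, 38 were higher in A, with a median difference of 0.81 on the log2 scale or 1.76-fold. Transferrin (tfa) had a value of 12758 in A and 2207 in B, alpha-1-antitrypsin (serpina1) 4796 and 1567, and the vitamin D binding protein gene gc 610 and 84.9. Other members hardly differed, such as the plasminogen gene plg with 796 and 793 and ambp with 1691 and 1728. The liver transcription factor list also stood apart towards A by 0.43. The median was 0.20 with a pseudocount of 10. Of its highest members, cebpb had 169 in A and 118 in B, cebpd 181 and 88.3 and cebpa 92.9 and 54.4, while hhex went the other way with 55.5 and 115. Exocrine pancreas markers were also higher in A, by a median of 8.27-fold, and skeletal muscle markers were higher in B by 6.62-fold.

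Most lists of metabolic genes were higher in library A than in B. The list of cholesterol synthesis genes had the largest difference among the metabolic lists: 24 of 25 members were higher in A, 18 of them at least 2-fold, with a median of 1.97 or 3.92-fold (1.21 with a pseudocount of 10). The exocrine pancreas markers moved in the same direction by 8.27-fold. Examples from the cholesterol synthesis list are the sterol demethylation enzymes msmo1 (423 in A, 44.2 in B) and cyp51 (235 and 26.2). Others are the mevalonate pathway enzyme hmgcs1 (297 and 54.2) and fdps (82.5 and 21.5). The gluconeogenesis and glycogen list differed by 0.77, with pck1, the enzyme that makes phosphoenolpyruvate in gluconeogenesis, at 1406 and 455. The bile acid synthesis list differed by 0.72 over 8 members, fatty acid and triglyceride synthesis by 0.60, xenobiotic metabolism by 0.57, amino acid and urea metabolism by 0.54, and fatty acid oxidation and peroxisomes by 0.40. With a pseudocount of 10 the bile acid list differed by 0.41, fatty acid synthesis by 0.23 and xenobiotic metabolism by 0.27. Xenobiotic metabolism differed by 0.31 among genes with a mean of at least 10. Within these lists, the esterase gene ces2 had a value of 1194 ± 826, the methyltransferase gene bhmt 3928 ± 2700, and the acyl-CoA dehydrogenase gene acadm 793 ± 74.7. The glycolysis and hypoxia list went the other way, by -0.38, with 20 of 30 members higher in B (-0.20 with a pseudocount of 10). Skeletal muscle markers, which share the enolase gene eno3 with this list, were also higher in B, by 6.62-fold, while eno3 itself had 1250 in A and 1140 in B. Oxidative phosphorylation genes had a median at percentile 96.0 in A and 96.2 in B. They differed by -0.14, inside the range of random lists.

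Cell cycle genes were expressed at low to intermediate rank and were higher in library B. The S-phase list, genes of DNA replication and nucleotide supply, had a median at percentile 42.8 in A and 51.5 in B. Of its 54 members above the filter, 46 were higher in B, with a median difference of -0.72 (log2, A minus B) or 1.65-fold; with a pseudocount of 10 the median was -0.22. The replication clamp gene pcna had values of 73.9 in A and 175 in B, and the replicative helicase gene mcm7 24.9 and 48.7. The G2/M and mitosis list lay lower, at percentile 25.9 in A and 36.6 in B, and 41 of 44 members were higher in B, by a median of 2.02-fold. Its median difference was -1.01, and -0.27 with a pseudocount of 10. The mitotic kinase genes cdk1 (2.93 and 11.2), plk1 (3.95 and 10.5) and aurkb (4.36 and 11.7) are examples. The highest levels in this list were those of the tubulin gene tubb4b (331 and 599) and the chromatin protein gene hmgb2a (41.0 and 176). DNA damage and repair genes differed by -0.33, histone and chromatin genes by -0.34, ribosome biogenesis genes by -0.40 and splicing genes by -0.33, and each of these lists stood apart towards B. With a pseudocount of 10 the medians were -0.11, -0.18, -0.24 and -0.24. Among genes with a mean of at least 10, the histone list differed by -0.53, and the 7 repair genes left differed by -0.24, within the random range. The markers of skeletal muscle and skin described below were also higher in B, by medians of 6.62-fold and 2.29-fold.

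Lists for apoptosis and cell cycle arrest did not stand apart between the libraries, with median differences of 0.13 and -0.06. The direction of the second turned to 0.07 among genes with a mean of at least 10. Among apoptosis genes, the pro-apoptotic gene baxa had values of 18.3 and 18.4, diabloa, whose product binds inhibitors of apoptosis, had 962 in A and 252 in B, and mcl1a, an anti-apoptotic gene, had 118 ± 16.2. In the cell cycle arrest and senescence list the insulin-like growth factor binding protein genes igfbp1b (431 ± 48.0) and igfbp1a (287 ± 105) were highest. The cyclin-dependent kinase inhibitor gene cdkn1ba had 9.37 and 8.90. The gene cdkn1a was not analysed here. The list of oncofetal and progenitor genes differed by 0.07, and by -0.17 among genes with a mean of at least 10, within the random range both times. Its members included epcam (30.7 and 167), an epithelial adhesion gene that also stands in the skin and biliary lists, the immediate early genes jun (68.6 ± 5.90) and egr1 (68.4 ± 46.3), and mycb (28.3 and 28.0). Germline and piwi genes were near the lowest values, with a median value of 0.63 in A and 0.69 in B. Their difference of 0.39 rested on 5 members and lay inside the random range.

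The unfolded protein response list was higher in A by 0.36, with 36 of 44 members in that direction (0.21 with a pseudocount of 10). Exocrine pancreas markers were higher in A too, by 8.27-fold. Some of the highest members of the unfolded protein response list differed little or went the other way. The endoplasmic reticulum chaperone gene hspa5 had 294 in A and 287 in B, and xbp1 had 389 and 441. Heat shock and chaperone genes differed by 0.06, led by hspa8 (2620 ± 326) and hsp90ab1 (2134 ± 179). Acute phase and complement genes differed by 0.10 (0.01 without a filter), and the fibrinogen genes fga (1293 ± 60.0), fgb (1222 ± 84.9) and fgg (1015 ± 166) varied little. The interferon response list was lower in A by -0.35, just outside the random range of -0.34 to 0.30. It lay inside the range with a pseudocount of 0.1 (-0.38), without a filter (-0.14) and among the 5 genes with a mean of at least 10 (-0.49). Macrophage and neutrophil markers were higher in B by 2.01-fold. Antiviral members of the interferon response list were low, with irf7 at 4.35 and 6.32 and stat1a at 4.65 and 5.51. The gene rsad2 had 1.06 in A and was listed at 0 in B, while isg15 had 29.5 and 19.8.

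Markers of cells other than hepatocytes gave the largest list medians in each direction, those of exocrine pancreas and skeletal muscle. Exocrine pancreas genes were higher in A: 17 of 18 members, 16 of them at least 2-fold, with a median difference of 3.05 or 8.27-fold. The trypsinogen gene try had 3681 in A and 469 in B, the chymotrypsinogen gene ctrb1 1741 and 180, the elastase gene ela2 1501 and 138, and the amylase gene amy2a 307 and 14.1. One elastase gene, ela2l, went the other way with 4.02 and 36.4. Skeletal muscle genes were higher in B: 27 of 30 members, 25 of them at least 2-fold, with a median of -2.73 or 6.62-fold (-1.61 with a pseudocount of 10). The muscle actin gene actc1b had 76.5 in A and 912 in B, the parvalbumin gene pvalb2 75.5 and 905, the myosin light chain gene mylpfa 39.0 and 458, and the muscle creatine kinase gene ckma 8.03 and 147. Skin epithelium genes were higher in B by 2.29-fold, a median of -1.20 (-0.70 with a pseudocount of 10), with 12 of 21 at least 2-fold higher, among them the keratin genes krt4 (69.4 and 160) and krt5 (24.1 and 97.4).

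Immune and support cell markers were higher in B, by less than the muscle markers. Macrophage and neutrophil genes were higher in B by 2.01-fold, or by -0.42 on the log2 scale (A minus B) with a pseudocount of 10, with the macrophage gene mpeg1 at 3.40 and 17.8 and the leukocyte gene coro1a at 6.83 and 36.4. Stellate cell genes, of which 9 of 22 also stand in other lists, were higher in B by 1.76-fold, a median of -0.82 (-0.33 without a filter), with hand2 at 12.0 and 22.1 and acta2 at 3.82 and 10.3. Biliary genes, 6 of 19 of them shared with other lists, were higher in B by 1.47-fold, a median of -0.55 (-1.35 among genes with a mean of at least 10), with the keratin genes krt8 at 577 and 1444 and krt18 at 418 and 926. Extracellular matrix genes were higher in B by 1.25-fold, a median of -0.33 (-0.11 with a pseudocount of 10), with col1a1a at 6.71 and 25.9, and fn1b going the other way at 62.0 and 10.6. Endothelial genes were higher in B by 1.23-fold, a median of -0.30, and lay inside the random range without a filter (-0.19), with kdrl at 7.06 and 8.20. Intestinal genes differed by -0.39, with fabp2, an enterocyte fatty acid binding protein gene, at 115 and 151, and the apolipoprotein gene apoa4 going the other way at 2588 and 1273. They lay inside the random range with a pseudocount of 10 (-0.13) and among genes with a mean of at least 10 (-0.085). Erythrocyte genes differed by 0.37, inside the random range, and their direction turned to -0.53 among the 7 genes with a mean of at least 10. Their embryonic globin genes hbae3 (663 and 1035) and hbbe1.1 (614 and 1048) went the other way from the list median.

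**Figure D1:**
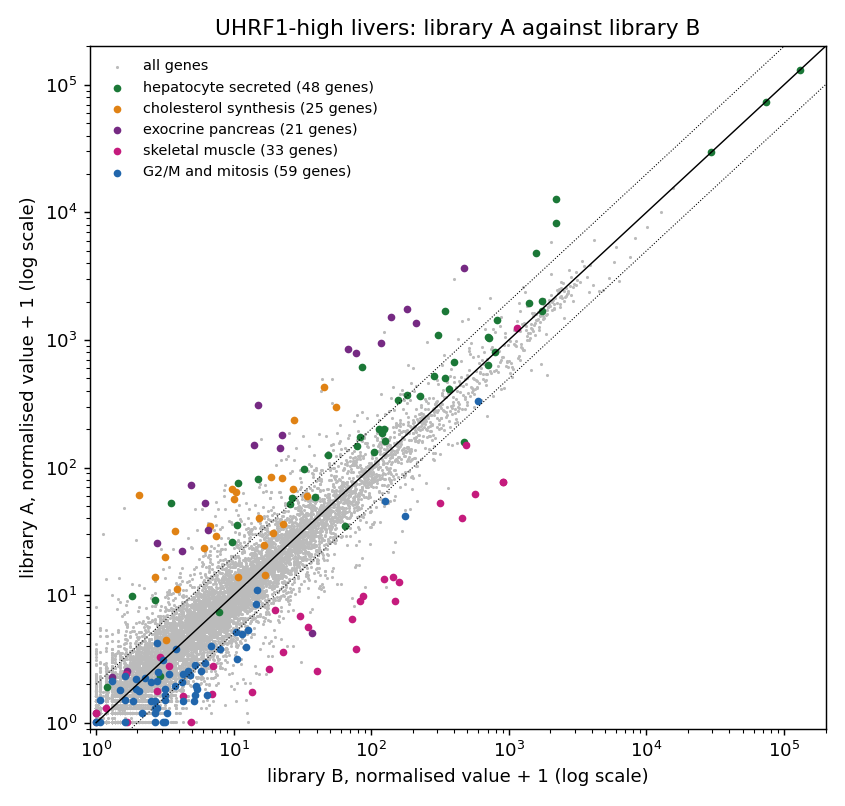
Normalised value + 1 of each gene in UHRF1-high library A (vertical, log scale) against library B (horizontal, log scale), with 11021 genes in grey and the measured members of 5 gene lists in colour. The solid line marks equal values and the dotted lines a 2-fold difference; most exocrine pancreas and cholesterol synthesis genes lie above the solid line, and most skeletal muscle and G2/M genes below.

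Across all 11021 genes the libraries had a Pearson correlation of 0.955 on the log2 scale and a Spearman correlation of 0.935, where genes are not independent replicates. Of the 8386 genes above the filter, 86.1% differed by less than 2-fold. There were 593 genes at least 2-fold higher in A and 573 at least 2-fold higher in B, and 109 and 78 at least 4-fold. The 2-fold counts were 889 and 854 with a pseudocount of 0.1, 188 and 134 with a pseudocount of 10, and 320 and 238 among genes with a mean of at least 10. Only 77 genes had an identical value in both libraries, so the columns of A and B are not copies of each other. Whether they hold separate RNA samples cannot be read from this count. The 10 named genes with the largest difference towards A were ins, cfhl2, amy2a, cel.1, cpa5, c6ast3, ela2, cpa4, ctrl and ctrb1. The insulin gene ins led them with 46.8 in A and 0.609 in B, and 7 of these genes belong to the exocrine list. The 10 towards B were atp2a1, ckma, atp2a1l, tpma, ckmt2, pvalb2, actc1b, mylpfa, myhz1.1 and pvalb4, of which 8 belong to the skeletal muscle list. The calcium pump gene atp2a1 led these with 2.75 in A and 76.7 in B. Of the 37 lists fixed in advance, 11 stood apart towards A, 16 towards B and 10 lay within the random range.

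**Figure D2:**
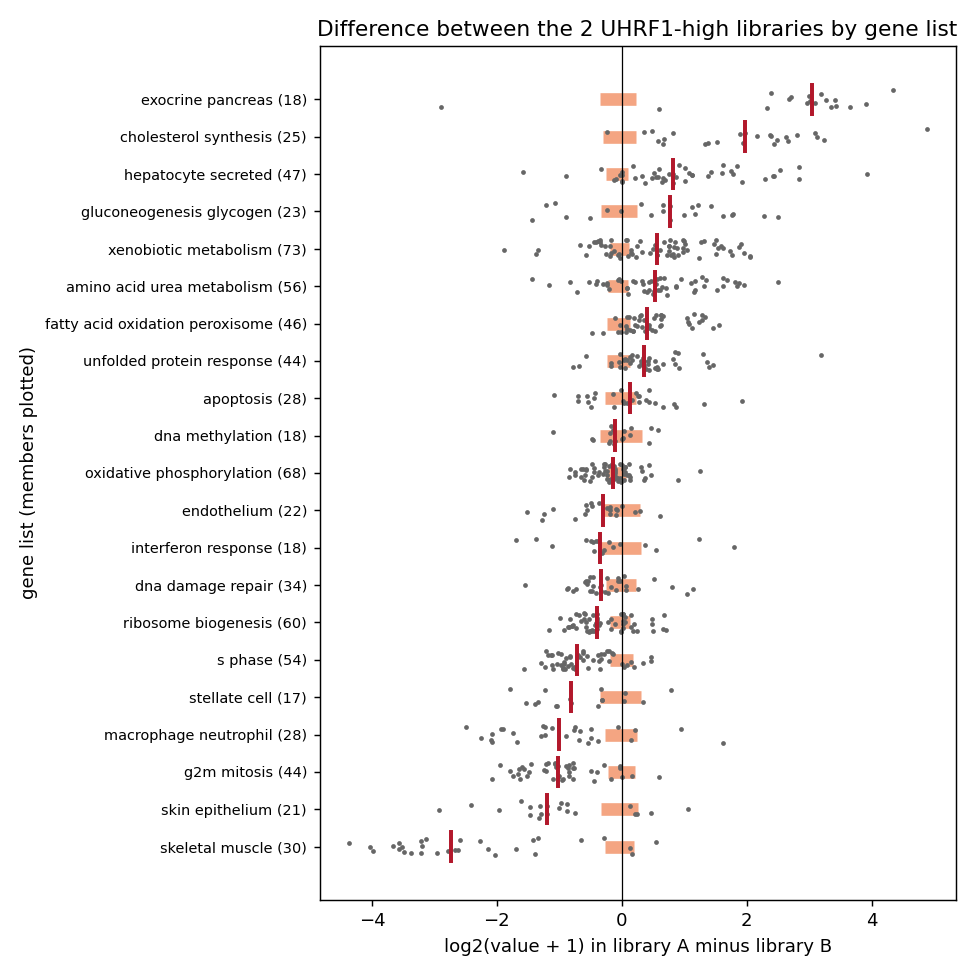
Difference in log2(value + 1) between library A and library B (horizontal) for the members above the filter of 21 gene lists (vertical, number of members in brackets). Grey points are genes, red bars the list medians and pale bars the central 95% of medians of 10000 random lists matched on level; the medians run from 3.05 for exocrine pancreas to -2.73 for skeletal muscle.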

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

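All alternatives here were chosen after seeing the data, because the planned ones compare the UHRF1-high and control groups and were not run. Each of the 27 lists that stood apart kept its direction in every alternative that gave it a value: 0 of 178 list medians reversed, and 47 moved by more than the SD of random medians. Of those 27, 26 still lay outside the random range with a pseudocount of 0.1, 26 with a pseudocount of 10 and 25 without a filter, as did 21 of the 24 that had a value with a filter at a mean of 10. The lists that came to lie inside under at least 1 of these were interferon response, intestine, endothelium and DNA repair. Erythrocyte genes came to lie outside, towards A, without a filter (0.46) and after a further quantile normalisation. The size depended on the pseudocount: with 10, 20 of the 27 medians were over 1.5 times smaller. With a pseudocount of 10 the genes at least 2-fold higher numbered 188 in A and 134 in B instead of 593 and 573, and the medians (log2, A minus B) were -0.22 for S phase, -0.27 for G2/M, 1.21 for cholesterol synthesis, 2.61 for exocrine pancreas, -1.61 for skeletal muscle and -0.70 for skin. With a pseudocount of 0.1 the counts were 889 and 854 and the medians -0.88 for S phase, -1.40 for G2/M, 2.12 for cholesterol synthesis and -3.25 for skeletal muscle. Without a filter G2/M was -0.86 and skin -0.99. With a filter at a mean of 10, where fewer genes were tested, 320 genes were 2-fold higher in A and 238 in B, Spearman's rho was 0.828 (0.908 at the main filter), and the medians were -0.94 for S phase, -0.85 for G2/M and -3.22 for skeletal muscle. Median scaling, a further quantile normalisation and leaving out marker genes moved none of these counts, correlations or medians past those bounds, and the first 2 change the values little by construction. A mean over 2 libraries lies within 1 SD of each of them by construction, so using 1 library alone says nothing about stability. No paired analysis was possible because the control group was not analysed and the labels letter one group and number the other. Depth is unknown, so values near the lowest step, such as those of dnmt3aa or foxm1, cannot be told from no signal.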

Other observations

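Genes of further tissues, in lists added after the values were seen, also differed between the 2 UHRF1-high libraries. Hormone genes of the pancreatic islet were higher in A, with ins at 46.8 and 0.609, sst1.1 at 9.09 and 0.304, gcgb at 7.81 and 0.487 and sst2 at 6.998 and listed at 0 in B. The islet genes pdx1 (5.57 and 10.5) and gcga (4.77 and 5.28) were not. The medians of these lists depend on the filter, which most islet, fin fold and neural members did not pass. Fin fold genes were higher in B by a median of 4.92-fold or -2.30 (log2, A minus B) over 7 genes, and by -0.30 without a filter and -0.76 with a pseudocount of 10, among them the actinodin genes and2 (2.01 and 29.9) and and3 (1.79 and 13.2). Smooth muscle genes, of which 5 of 9 measured also stand in other lists, were higher in B by 1.96-fold over 7 genes. Cardiac muscle genes, 2 of 16 of them shared with other lists, were higher in B by 1.56-fold over 8 genes. With a pseudocount of 10 these medians were -0.58 and -0.28. Neural genes differed by -0.57 over 14 genes, by -1.16 with a filter at a mean of 10, and by -0.056 without a filter, inside the random range. Kidney genes differed by 0.04 (log2) over 7 genes. The eye list had 3 members above the filter and was not summarised.

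The tests that follow were chosen after the patterns were seen, except the cartilage test, whose prediction was written before its values were looked at. A and B belong to the same group, so no explanation through the study's groups was tested. Intervals over genes treat them as independent and hold for these 2 libraries only. Exocrine pancreas genes were 8.27-fold higher in A. A candidate explanation is more pancreatic tissue collected with the liver in A than in B, where try still had a value of 469. The 6 islet genes had a median difference of 2.76 in the same direction. It was 0.76 with a pseudocount of 10 and 0.24 over all 22 genes without a filter. Each of these medians lay above the random range. However, 3 of the 6 had been seen before the test was written and 2 of the other 3 did not follow, which leaves this open.

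Skeletal muscle and skin genes were higher in B. A lower share of hepatocyte RNA in B alone would raise the markers of all other cell types alike. It is argued against as the whole cause for the muscle genes. Their median lay -2.43 (log2) from the endothelial median, with a 95% bootstrap interval over genes from -3.02 to -1.66. This gap depends on the comparator: endothelial genes had a lower median level (4.33 against 19.1) and shifted less than skin, macrophage, stellate and biliary genes. Gaps to those lists are smaller, and no intervals were computed for them. Exocrine pancreas genes, also markers of another cell type, were higher in A by a median of 3.05, with 17 of 18 members in that direction. A lower share of hepatocyte RNA in B alone would not give this. Among genes with a mean of at least 10, the medians were -3.22 for muscle, -1.35 for biliary and -1.20 for skin genes. A candidate explanation is more body wall tissue collected with the liver in B than in A, where actc1b still had a value of 76.5. Cartilage and notochord genes had a median of -1.07, in that direction, but only 6 members passed the filter, and without a filter the median of all 18 turned to 0.044, so this stays open. Cell cycle genes were also higher in B, and whether they came from hepatocytes or from such tissue was not tested.

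Cholesterol synthesis genes were 3.92-fold higher in A. A general difference in lipid synthesis is argued against as the whole cause: their median exceeded that of the fatty acid and triglyceride synthesis list by 1.37 (log2), with an interval from 0.531 to 2.04, and among genes with a mean of at least 10 the medians were 2.07 and 0.88. A lower share of hepatocyte RNA in B is a candidate explanation that most values go against as the whole cause: the cholesterol median exceeded that of all 47 hepatocyte genes by 1.16, with an interval from 0.448 to 1.80, and that of the 22 no higher than the highest cholesterol gene by 0.93, from 0.0932 to 1.68. Normalisation fixes the top ranks among the 47, but 38 were higher in A and 6 in B. The interval for all 47 stayed above 0 with a pseudocount of 10 (0.101 to 1.04). The explanation was left open because the interval for the 22 included 0 with a pseudocount of 10 (-0.067 to 0.97). A comparison with the hepatocyte gene nearest in level, run last because the 22 had a median level of 47.6 against 26.6, gave 0.96 with an interval from -1.07 to 1.93 and rests on only 11 hepatocyte genes.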
